A study of Iris tectorum with 6 samples.

How the data were processed

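Leaf RNA of Iris tectorum, a rhizomatous garden iris, was sequenced after growth in swine wastewater in a glasshouse where the water stood 12.3 cm high on average (± 0.8 cm), per the labels' protocols. Plants were grown alone or together with Dictyosphaerium sp., a colonial green microalga. The labels give 3 samples per group, numbered 1 to 3. Files of 5 libraries were analysed, 2 of plant alone (replicates 2 and 3) and 3 of co-culture (replicates 1, 2 and 3), and plant alone replicate 1 was not analysed here. RNA was extracted with a plant RNA kit, fragmented, reverse transcribed with random primers and sequenced on a BGISEQ-500 instrument, per the labels' protocols. The labels state polyA RNA, while the extraction text leaves open whether oligo-dT selection or rRNA depletion was used.

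Bowtie2, RSEM and DESeq2 were named without versions in the submitters' processing notes. Each library's file held an RSEM expected count and an FPKM value per unigene (fragments scaled to transcript length and library total), per the file headers, and the authors listed in it only unigenes that had reads in that library. A unigene is an assembled transcript. Its reference was an assembled transcriptome whose contigs carry cluster numbers, so near-identical contigs of one cluster can share reads. The assembler was not given in the sources used here. The files gave a best protein hit in the nr database with its species, and KEGG orthology and gene ontology terms. A deposited table of the authors' comparison held pooled expected counts per group, a log2 ratio of co-culture over plant alone, a p-value and a q-value, per the file headers. Its file name pointed to DEGseq, whereas the processing notes named DESeq2. A second deposited table listed called unigenes matched to plant resistance genes, with the same log2 ratio.

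The pooled plant alone column of the authors' deposited table summed to 59625013, against 37498927 in the 2 plant alone libraries analysed here. The pooled co-culture column summed to 66856619, against 66856674 in the 3 co-culture libraries. The authors' plant alone values therefore included reads not analysed here. No library was rebuilt by subtraction.

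A unigene missing from a library's file was set to 0. Expected counts were rounded to whole numbers. The main test was edgeR 4.0.16 (R 4.3.3), with its default filter on low counts, TMM scaling and quasi-likelihood F tests without a replicate block. P-values were adjusted by the Benjamini-Hochberg method at 0.05. Levels are TMM-scaled CPM, given as mean ± SD over libraries, and fold changes are co-culture over plant alone. DESeq2 1.42.0 was run as an alternative on the same counts, and its missing adjusted p-values were left missing. Where all libraries of a group were at 0, the fold is a lower bound against 3 counts over that group. Such bounds cover counting error only. A count of 3 corresponded to between 0.13057 and 0.16114 CPM per library.

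The main test, 29 gene lists, 6 lists of other organisms and most alternatives were fixed before the data were examined. The DESeq2 fit of cluster sums, voom with library quality weights, other memberships of the lists and the restriction to monocot hits were added after seeing the data. Fry had been named beside camera when the tests were fixed, and was added to the alternatives after seeing the data. Lists were matched by words in the product name, or by a single KEGG identifier where the product was unnamed. The rule as first fixed took any KEGG identifier, and was narrowed after the annotation was seen and before any test was run, because identifiers could contradict the product. With the rule as first fixed, 8 lists passed camera, 5 upward and 3 downward. The lists were tested with camera (limma 3.58.1) at a preset correlation between genes of 0.01, and also with an estimated correlation and with fry. The organism lists were matched to the species of the protein hit, and their share of counts was compared by an exact two-sided permutation test, which cannot go below p = 0.1 for 2 against 3 libraries. The rule for named unigenes took, first, the 10 largest changes in each direction among unigenes past the edgeR threshold with an annotated product, non-overlapping libraries and at least 5 CPM. Second, it took the 2 members with the smallest adjusted p in each direction from every list that passed camera, and last, the best member of any other list if it passed. The first and last parts named none. The first part was therefore repeated on DESeq2 calls, a choice made after seeing the data, as was a list of 44 monocot genera used to sort protein hits.

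The count tests were tested on simulated data with 200 changed unigenes. With the spread of these libraries (63963 unigenes), edgeR recovered 0% of 4-fold and 0% of 16-fold changes at adjusted p 0.05. DESeq2 recovered 21% and 82% of them and made 468 false calls. The changed unigenes were drawn from the more abundant ones, and none was set to 0 in a group. Both groups were simulated with the same spread, whereas the real co-culture libraries were further apart than the plant alone ones. These shares and false calls therefore need not hold for the real data. With a spread of 0.2 (66056 unigenes), edgeR recovered 100% of either size. In the simulated comparison with the libraries' spread, camera passed the shifted list and not the unchanged one. The simulated unigenes were drawn independently, so their lists held no correlation between genes. In the real data, the lists that passed camera had estimated correlations from 0.036 (ribosome) to 0.516 (light harvesting), all above the preset one. The simulation therefore cannot decide how often camera passes unchanged lists with such correlations.

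Alternatives were median-ratio size factors, library totals, other count filters, a replicate block, each library left out, log2(FPKM + 1) and log2(FPKM + 0.1) with limma, contigs summed per cluster, other thresholds, and other memberships of the lists. Figures were drawn with matplotlib 3.10.9.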

Results

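Leaves of Iris tectorum grown in swine wastewater were profiled by RNA sequencing in 2 settings, the plant alone and the plant in co-culture with the green microalga Dictyosphaerium sp. The 5 libraries comprised 2 of plant alone and 3 of co-culture. Plant alone replicates 2 and 3 held 18881996 and 18616931 expected counts. Co-culture replicates 1, 2 and 3 held 22912284, 22975621 and 20968769. In all, 111791 unigenes had reads in at least 1 library, and 60409 of them (54.0%) had a protein hit. The most frequent species of the hits was Asparagus officinalis, with 19338 unigenes. Nothing in the labels says that the samples came from separate cultures, so p-values measure the spread between these samples.

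The libraries of the co-culture group were far apart. Rank correlations across unigenes, which are not independent replicates, were 0.831 between the plant alone libraries and also 0.831 between plant alone 2 and co-culture 1. Among the co-culture libraries they were 0.759 for replicates 1 and 2, 0.704 for 1 and 3, and 0.686 for 2 and 3. The biological coefficient of variation estimated by edgeR was 0.773.

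**Figure D1:**
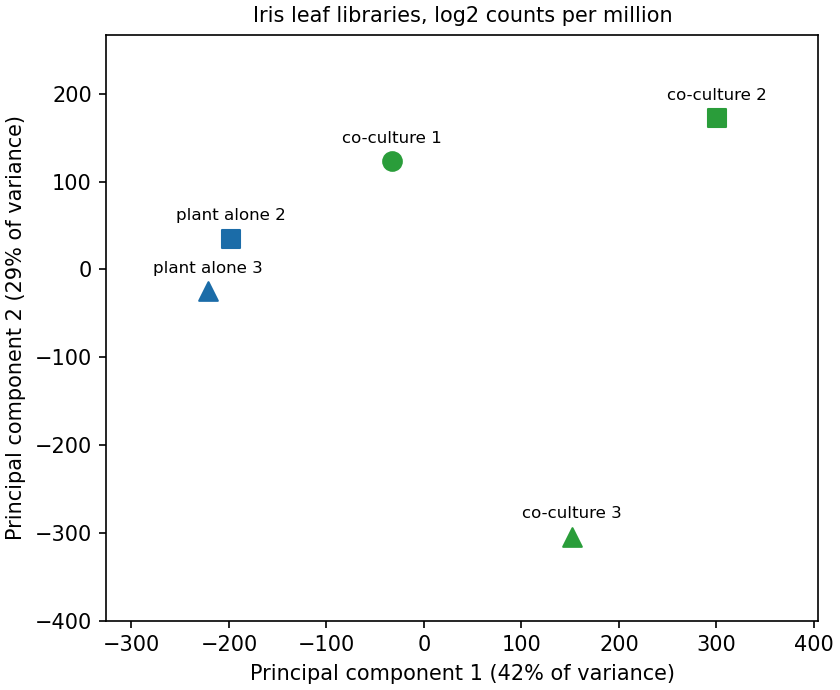
Principal components 1 and 2 of log2 CPM, with 1 point per library, blue for plant alone and green for co-culture. The plant alone libraries lie together at -198 and -221 on component 1, and the co-culture libraries are spread from -32.7 to 300.2.

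The first question was which transcripts differed between leaves grown with and without the alga. Among the largest differences called by DESeq2 were single contigs for water transport, sulfur assimilation and RNA handling. A contig of the plasma membrane aquaporin PIP2-2 (CL3376.Contig4_zju), a water channel, had no reads in plant alone and 122.8 ± 121.7 CPM in co-culture (SD, n = 3), at least 1500-fold higher. Contigs for 5'-adenylylsulfate reductase (CL2714.Contig4_zju), an enzyme of sulfate assimilation, and for a cysteine synthase-like protein (CL7495.Contig6_zju) likewise went from 0 to 31.3 ± 37.8 and 36.2 ± 30.4 CPM, at least 381-fold and 441-fold higher. In the other direction, a contig for heterogeneous nuclear ribonucleoprotein R (CL1295.Contig9_zju), an RNA-binding protein, went from 49.6 ± 4.23 CPM (SD, n = 2) to 0, at least 1110-fold lower. Summed over their clusters, the log2 fold changes were 1.09 for PIP2-2, 1.03 for the reductase, 0.11 for cysteine synthase and 0.02 for the ribonucleoprotein, whose cluster also holds nucleolin contigs. DESeq2 called none of these cluster sums, and none of these contigs passed the edgeR test. Without co-culture 2, the fitted log2 fold changes of the PIP2-2 and reductase contigs went from 14.31 and 12.34 to 13.11 and 10.68, and without co-culture 3 that of the cysteine synthase contig went from 12.55 to 11.87.

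Of 69984 unigenes tested, edgeR called 0 at adjusted p 0.05, and the smallest adjusted p was 0.628. At unadjusted p under 0.05, edgeR gave 5036 (7.2%), of which 1925 were higher and 3111 lower in co-culture. Among unchanged unigenes simulated with the spread of these libraries, 4.5% had such an edgeR p-value. DESeq2 called 1313 unigenes, 629 higher and 684 lower, and gave no adjusted p for 4200. In simulation with the spread of these libraries it made 468 false calls, so its calls can include many false ones. Among 39822 tested unigenes with a monocot hit, 466 calls were higher and 213 lower, and among 21276 without a hit 77 and 293. Among 481 on the organism lists they were 7 and 24, and among 8405 with any other hit 79 and 154. Every co-culture library lay above every plant alone library for 12.8% of unigenes and below for 17.2%, where chance gives 10% for each.

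The other DESeq2 calls named by the rule included metal tolerance protein 5-like (CL5240.Contig4_zju), a cation transporter, at 0 against 30.9 ± 45.3 CPM. A root-type ferredoxin-NADP reductase (CL8852.Contig1_zju) stood at 0 against 19.8 ± 16.1 CPM. In the authors' pooled comparison, which held plant alone reads not analysed here, their log2 ratios were 3.38 and 11.26. The absence of the metal tolerance contig may thus hold only for the plant alone libraries analysed. A contig of 40S ribosomal protein S7 (CL15235.Contig3_zju) averaged 163.1 ± 263.5 CPM in co-culture, with 0.134 CPM in replicate 1 and 467.1 in replicate 3. Contigs at 0 in co-culture included chloroplastic glyceraldehyde-3-phosphate dehydrogenase B (CL3120.Contig7_zju, 16.9 ± 19.2 CPM in plant alone) and ABC transporter G family member 39 (CL1906.Contig6_zju, 16.04 ± 17.2 CPM). These are contigs of clusters that can share reads. The cluster of the dehydrogenase contig went the other way, with a log2 fold change of 1.41, as did that of the ferredoxin-NADP reductase contig at -0.56, and the cluster sums were 0.25 for metal tolerance protein, 0.22 for S7 and -0.18 for the ABC transporter. The fitted log2 fold changes of the contigs went from 12.32 to 9.62 for metal tolerance protein without co-culture 2, from 11.68 to 10.72 for the ferredoxin-NADP reductase without co-culture 3 and from 14.72 to 15.33 for S7 without co-culture 1. Without co-culture 2 or co-culture 3, the S7 contig did not pass the count filter. Those of the dehydrogenase and the ABC transporter went from -11.45 to -9.14 without plant alone 2 and from -11.38 to -9.36 without plant alone 3, and to -12.33 and -12.22 without the other library. Nucleolin had a contig that went from 0 to 24.8 ± 6.49 CPM (CL1295.Contig12_zju) and another of the same cluster that went from 27.5 ± 4.96 CPM to 0 (CL1295.Contig3_zju), while the sum over the cluster had a log2 fold change of 0.02. With contigs summed per cluster, DESeq2 called 804 of 44185 entries, 243 higher and 561 lower, and edgeR called 0, with 4165 at unadjusted p under 0.05. Of the unigenes that the rule took from DESeq2 calls, only protease Do-like 7 (Unigene11215_zju), which belongs to no cluster, was also called among these entries. It went from 7.145 ± 7.348 CPM, with 12.34 and 1.95 in plant alone 2 and 3, to 0. Its log2 fold change, -10.21, was -8.37 without plant alone 2.

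The second question was whether groups of genes moved together. Members of a gene list are unigenes, and contigs of one cluster enter camera as separate members. The 73 light harvesting members gave 39 entries when summed per cluster, and camera was not run on cluster sums. Of 29 lists, 7 passed camera at its preset correlation, 5 upward and 2 downward. None passed with an estimated correlation (smallest adjusted p = 0.525) or by fry (smallest adjusted p = 0.275), and fry's test for change in either direction passed for 8 lists, of which the ribosomal list was the only 1 among the 7. The others were phosphate starvation, auxin, ethylene, abscisic acid, housekeeping, cell wall and salicylate. Within the 7 lists, no unigene passed edgeR, also when adjusted over the list alone. At unadjusted p under 0.05, edgeR gave 17 higher and 3 lower heat shock members and 5 higher and 55 lower ribosomal members. DESeq2 adjusted over the list alone called from 2 members (WRKY factors) to 52 (ribosomal proteins).

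Heat shock proteins and factors, chaperones and their regulators, were shifted upward, with 152 of 210 members higher and a median log2 fold change of 0.60 (camera adjusted p = 1.66e-05, adjusted p = 0.726 with an estimated correlation). The medians of the 3 co-culture libraries were 0.38, 0.97 and 0.30 above the plant alone mean, and all exceeded those of plant alone (-0.14 and 0.14). A chloroplastic small heat shock protein (Unigene30866_zju) stood at 1.13 ± 0.468 CPM in plant alone and 23.2 ± 22.5 CPM in co-culture, a log2 fold change of 4.35 ± 1.05 (SE; DESeq2 adjusted p = 0.00206, edgeR adjusted p = 0.628). An unnamed protein placed in the list by its KEGG identifier (CL6231.Contig1_zju) stood at 0.407 ± 0.0895 and 9.65 ± 2.86 CPM. On the lower side, an unnamed protein with an Asparagus hit (Unigene2181_zju) had 41.2 ± 0.983 and 11.4 ± 7.57 CPM, with every co-culture library below plant alone. A heat shock protein 70 unigene of 220 bases whose hit was to a cryptophyte (Unigene23161_zju) had 0.773 ± 0.205 and 0.166 ± 0.0937 CPM. Without plant alone replicate 2, the camera call was lost (adjusted p = 0.112). Without co-culture 2, the list median was 0.32 and the small heat shock protein had a log2 fold change of 3.21.

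Genes of the photosynthetic light reactions were shifted upward as lists, and co-culture 3 went the other way. Light harvesting proteins, which bind chlorophyll in the antenna, had 64 of 73 members higher and a median log2 fold change of 1.08 (camera adjusted p = 1.66e-05, adjusted p = 0.726 with an estimated correlation). Photosystem and electron transport genes had 92 of 117 members higher and a median of 1.04 (camera adjusted p = 0.00908, adjusted p = 0.726 with an estimated correlation). The light harvesting medians were 1.38 and 1.86 above the plant alone mean in co-culture 1 and 2, and -0.80 in co-culture 3. The photosystem medians were 1.08, 1.85 and -1.05. Chlorophyll a-b binding protein 8 (CL958.Contig3_zju) had 0.267 ± 0.215 and 7.14 ± 6.46 CPM, and photosystem I subunit XI (CL13731.Contig2_zju) had 1.71 ± 0.391 and 11.3 ± 7.05 CPM. Their cluster sums had log2 fold changes of 1.23 and 1.20, and neither was called by DESeq2. Photosystem II 44 kDa protein (CL2684.Contig3_zju), an antenna protein encoded in the chloroplast, had 101 ± 25.2 and 20.5 ± 7.06 CPM. Also lower was an unnamed photosystem list member (CL7973.Contig1_zju), at 340.3 ± 29.5 and 73.5 ± 23.9 CPM (DESeq2 adjusted p = 0.00024). An unnamed light harvesting member (CL4290.Contig2_zju), without a DESeq2 call, had a lower mean, at 41.1 ± 6.95 and 21.8 ± 21.2 CPM. Its groups overlapped, with 46.1 CPM in co-culture 1 against 46.0 and 36.2 in plant alone 2 and 3. Its log2 fold change, -0.91, was -2.04 without co-culture 1 and -0.48 without co-culture 2. An unnamed light harvesting member (Unigene13306_zju) had a Chlorella variabilis hit, no reads in plant alone and 0.996 ± 0.339 CPM in co-culture. Without co-culture 2 the medians were 0.65 for light harvesting and 0.41 for photosystems, and without plant alone 2 the light harvesting median was 1.67. The log2 fold change of chlorophyll a-b binding protein 8, 4.70, was 5.88, 4.09 and 3.75 without plant alone 2, plant alone 3 and co-culture 2, and that of subunit XI, 2.72, was 2.13 without co-culture 2. The light harvesting call was lost without plant alone 3 (adjusted p = 0.0585) or co-culture 1 (0.105), and the photosystem call without plant alone 3 (0.352), co-culture 1 (0.143) or co-culture 2 (0.868).

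WRKY factors, plant regulators of stress and defence genes, were shifted downward, with 41 of 152 members higher and a median log2 fold change of -0.70 (camera adjusted p = 0.00356, adjusted p = 0.726 with an estimated correlation). The list medians were -0.34, -1.31 and -0.26 against the plant alone mean in co-culture 1, 2 and 3, and 0.36 and -0.36 in plant alone 2 and 3. WRKY 70 (Unigene5163_zju) stood at 8.43 ± 6.41 CPM in plant alone and 1.13 ± 0.343 in co-culture (DESeq2 adjusted p = 0.0207). WRKY 47 (CL8025.Contig2_zju) stood at 14.5 ± 0.441 and 4.30 ± 0.996 CPM (DESeq2 adjusted p = 0.00501), with a log2 fold change of -1.02 for its cluster sum. WRKY 69 (Unigene3510_zju) had 13.4 ± 1.30 and 46.3 ± 22.7 CPM, and WRKY 41 (CL3459.Contig4_zju) had 0.379 ± 0.13 and 2.21 ± 1.27 CPM, where its cluster sum had a log2 fold change of -0.95. That of WRKY 70, -2.89, was -1.79 without plant alone 2 and -3.49 without plant alone 3. The camera call was lost without plant alone 2 (median -0.0958, adjusted p = 0.5) or co-culture 2 (adjusted p = 0.128).

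Ribosomal protein genes were shifted downward by a small amount, with 499 of 760 members lower and a median log2 fold change of -0.20 (camera adjusted p = 0.0151, adjusted p = 0.726 with an estimated correlation). DESeq2 called 46 of them lower and 2 higher. The 484 members with a monocot hit had a median of -0.10, against -3.74 for the 30 members with a hit on the lists of algae, fungi, oomycetes and protists and -0.69 for the 245 with another hit. Of the 46 lower calls, 33 were among these 245, 9 among the 30 and 3 among the monocot hits. Without plant alone 3 the direction turned, with a median of 2.50 for the 30 members and 0.19 for the 275 members outside monocots. The members named on the higher side were 40S protein S10-1 (CL9237.Contig3_zju), at 16.4 ± 8.34 and 52.0 ± 21.7 CPM, and 60S protein L12 (CL7920.Contig3_zju), at 25.5 ± 1.54 and 69.2 ± 33.9 CPM, while their cluster sums had log2 fold changes of -0.33 and -0.79. The 60S protein L13A unigene (Unigene45503_zju) stood at 6.61 ± 1.16 CPM in plant alone and 0.235 ± 0.0756 in co-culture, 28.1-fold lower, and its hit was to a red alga, Galdieria. A large-subunit protein L10Ae unigene (Unigene6945_zju), with a cryptophyte hit, stood at 6.67 ± 0.997 and 0.375 ± 0.104 CPM. The list median was 0.0818 without plant alone 3 (adjusted p = 0.982), and the call was also lost without co-culture 1 (0.126), co-culture 2 (0.066) or co-culture 3 (0.117).

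Aquaporins had 21 of 36 members higher and a median log2 fold change of 0.42 (camera adjusted p = 0.0246, adjusted p = 0.726 with an estimated correlation). An aquaporin contig (CL15201.Contig2_zju) had 34.2 ± 2.14 CPM in plant alone and 88.6 ± 35.2 in co-culture (log2 fold change 1.37, cluster sum 0.80), and a PIP2-2 unigene (Unigene26330_zju) had 129.7 ± 17.0 and 87.6 ± 14.4 CPM. Aquaporin SIP2-1 (Unigene55421_zju) had 8.64 ± 0.679 and 6.12 ± 1.47 CPM. Starch and sucrose enzymes had 77 of 123 members higher and a median of 0.46 (camera adjusted p = 0.0246, adjusted p = 0.726 with an estimated correlation). Soluble starch synthase 2-2 (CL865.Contig1_zju), which extends starch chains, had 3.16 ± 0.477 and 11.5 ± 3.58 CPM (DESeq2 adjusted p = 0.0195), with a log2 fold change of 0.92 for its cluster sum, which DESeq2 did not call. Beta-amylase 1 (CL13540.Contig1_zju), which degrades starch, had 0 and 4.36 ± 4.55 CPM, and alpha-amylase 3 (Unigene37076_zju) had 100.2 ± 14.9 and 70.4 ± 6.89 CPM. The aquaporin medians were 0.79, 0.91 and -0.29 against the plant alone mean in co-culture 1, 2 and 3, and the starch and sucrose medians 0.44, 0.45 and 0. Without co-culture 2 the median was 0.20 for aquaporins and 0.22 for starch and sucrose, and the log2 fold change of the beta-amylase contig went from 9.50 to 8.21 (cluster sum 0.71). The aquaporin median was 0.23 without co-culture 1 and 0.72 without co-culture 3, and the starch and sucrose median 0.70 without plant alone 2. The aquaporin call was lost without plant alone 2 (adjusted p = 0.315), plant alone 3 (0.0585) or co-culture 1 (0.574), and the starch and sucrose call without plant alone 3 (0.258), co-culture 1 (0.143) or co-culture 2 (0.0543).

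**Figure D2:**
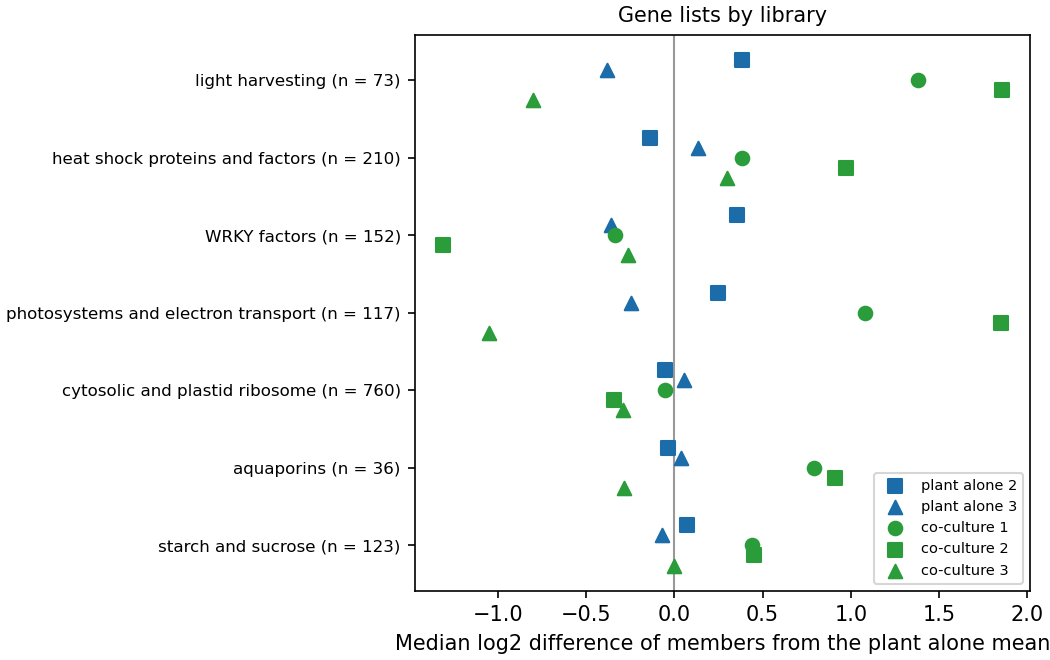
Median log2 difference from the plant alone mean over the members of each list that passed camera (x axis), with 1 point per library, blue for plant alone and green for co-culture. Co-culture 3 lies at -0.80 for light harvesting and -1.05 for photosystems, on the other side of 0 from co-culture 1 and 2.

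**Figure D3:**
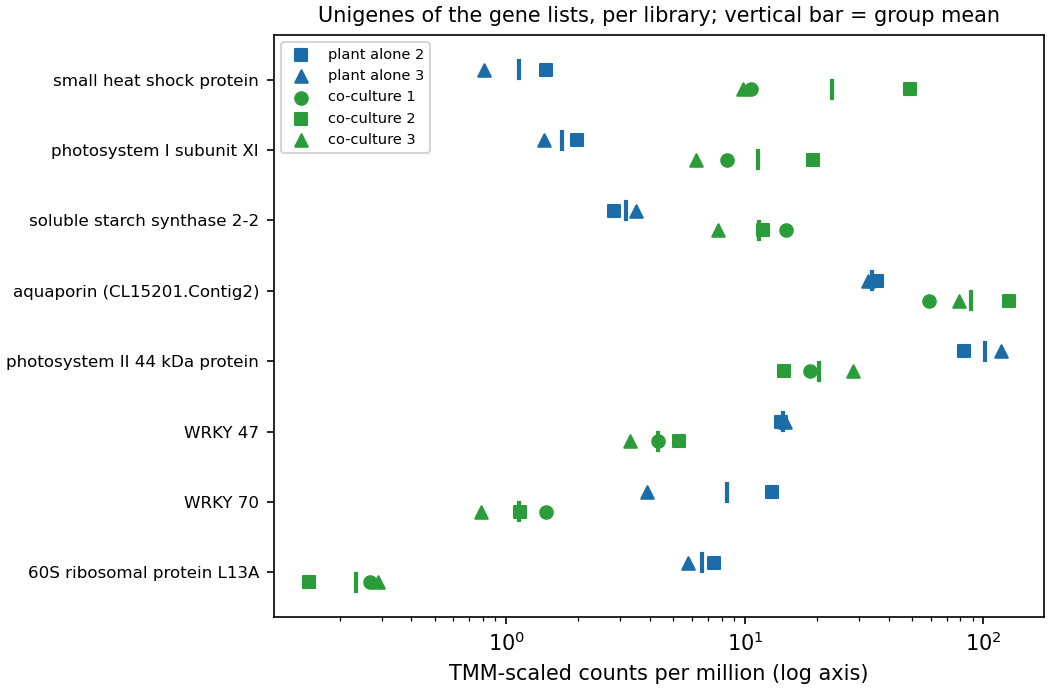
TMM-scaled CPM on a log axis for 8 unigenes of the lists, with 1 point per library and a vertical bar at the group mean. For WRKY 47 the plant alone mean is 14.5 and the co-culture mean 4.30, and no library of either group overlaps the other for any unigene drawn. The 8 were picked from the named members, some of which do overlap, so this does not describe the lists. In light harvesting, 6 of 73 members lay apart upward and 0 downward. Over all tested unigenes, 12.8% lay apart upward and 17.2% downward, so the upward count of this list does not exceed the general share.

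The other 22 lists did not pass camera. Closest were the phosphate starvation response (median log2 fold change -0.20, adjusted p = 0.0516), class III peroxidases (0.21, 0.0776), light signalling and clock (0.32, 0.0776), auxin (0.23, 0.113), chlorophyll synthesis (0.31, 0.113) and the Calvin cycle (1.35, 0.142). Nitrogen uptake and assimilation had a median of 0.11, hypoxia and fermentation 0.094, antioxidant enzymes 0.091 and glutathione S-transferases -0.30, where the mean was 0.21. Ethylene, abscisic acid and jasmonate lists had medians of 0.065, 0.095 and -0.093, and the means of the abscisic acid and jasmonate lists had the other sign (-0.016 and 0.29), with an upward camera direction for both. Phenylpropanoid and lignin genes had a median of 0.12, flavonoid and anthocyanin genes 0.45, and chlorophyll breakdown and senescence -0.33, where the mean was 0.063. ABC and metal transporters had 0.17, receptors of plant immunity 0.12, cell wall genes 0.11, DNA replication and histones 0.096, and housekeeping genes 0.047. The salicylate and pathogenesis-related list had a median of -0.022 and a mean of 0.0097, and 1 of its 127 members passed edgeR when adjusted over the list alone (0.0286). That member, singled out after its values were seen, was glucan endo-1,3-beta-glucosidase 14-like (Unigene54961_zju), at 158.6 ± 3.02 CPM in plant alone and 27.05 ± 4.78 in co-culture.

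The authors' deposited table of the comparison called 18303 unigenes up and 15229 down in co-culture among 112092. It compared pooled counts, in which the plant alone column held reads not analysed here, and gave no replicate error. Of its calls, 23979 were tested here, and 99.3% had the same sign in the edgeR fit. Because both rest on largely the same reads, this agreement was mostly given in advance. Libraries of the groups were apart in the same direction for 53.1% of the calls tested from the authors' deposited table, edgeR gave an unadjusted p under 0.05 for 19.5%, and 0 passed the adjusted threshold. DESeq2 called 1271 of them in the same direction. For 4975 of the up calls in the authors' deposited table (27.2%), a single co-culture library held over 80% of the group's counts, and for 3022 of these it was co-culture 3.

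The authors' deposited table of resistance genes, chosen from their calls on these samples, held 471 unigenes, 303 up and 168 down. The share up was 64.3%, against 54.6% among all the authors' calls. By the classes in the authors' deposited table, RLP held 138 up and 72 down, N 64 and 24, NL 27 and 26, CNL 20 and 14, and TNL 18 and 7. Of 358 tested here, edgeR called 0, with 61 (17.0%) at unadjusted p under 0.05, against 19.5% of the authors' other calls (Fisher's exact test, p = 0.254). DESeq2 called 13 higher and 4 lower, with an odds ratio of 0.889 against the authors' other calls (Fisher's exact test, p = 0.722). Most of the higher ones were contigs with no reads in plant alone, and most of the called unigenes had products not annotated as receptors, among them ABC transporters, a plant cysteine oxidase and a stearoyl-ACP desaturase. Of the receptors, picked after their values were seen, a STRUBBELIG-receptor family 8-like unigene (CL2215.Contig5_zju) stood at 8.25 ± 0.421 and 21.4 ± 1.58 CPM, and a receptor-like kinase TMK3 unigene (Unigene61944_zju) at 0.918 ± 0.485 and 9.90 ± 5.99 CPM. Because the edgeR calls were 0, their share inside and outside the table could not be compared.

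Reads were also counted by the species of the protein hits, which need not be the organism a read came from and were not checked by sequence. Hits on the 6 organism lists took 5252 ± 1966 CPM of the library total in plant alone (SD, n = 2) and 3345 ± 306 in co-culture (SD, n = 3), a difference of -1908 (exact permutation test, p = 0.1, the smallest possible). Plant alone 3 held 6642 CPM and plant alone 2 held 3863 CPM. Green algae took 3043 ± 397 and 2105 ± 146 CPM (exact permutation p = 0.1). Fungi and oomycetes took 1005 ± 903 and 427 ± 87.8 CPM (exact permutation p = 0.3), and ciliates and other protists 1204 ± 666 and 813 ± 72.8 CPM (exact permutation p = 0.4). The lists of animals, bacteria and viruses matched 0 unigenes.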

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

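The DESeq2 fit of cluster sums, the voom fit with library quality weights, the list memberships by text alone or any KEGG identifier (the latter being the rule first fixed, now run as an alternative), and the restriction to monocot hits were chosen after seeing the data, and fry, named beforehand beside camera, was added to the alternatives then; the others were planned. The count of unigenes past the threshold was 0 under every edgeR, limma and voom setting run. At unadjusted p under 0.05 these settings gave 1901 to 7028, while DESeq2 called 1313 unigenes and 804 cluster sums. In simulation with the libraries' spread, edgeR recovered 0% of 4-fold and 16-fold changes with 0 false calls, and DESeq2 made 468 false calls. Missed changes and false DESeq2 calls can thus both enter this gap, and their parts were not separated in the real data. The number of lists passing camera, 7, was between 2 and 9 with 1 library left out, 3 with log2(FPKM + 0.1), and 0 with an estimated correlation or fry. Only 2 replicate numbers occur in both groups, and the numbers were not taken to pair libraries because no pairing is stated. Deviations of same-numbered libraries correlated at 0.0371 and 0.0695. With 2 plant alone libraries their deviations mirror each other, so these correlations cannot decide on pairing. With the replicate block 0 unigenes and 3 lists passed. The block moved the list medians to 0.398 for light harvesting, 0.188 for photosystems, 0.167 for aquaporins, 0.284 for starch and sucrose and -0.313 for the ribosome. It ended the camera calls of photosystems (adjusted p = 0.116), aquaporins (0.453), starch and sucrose (0.116) and the ribosome (0.164). With at least 5 CPM in 2 libraries the ribosomal median was -0.073 (adjusted p = 0.274), and that call and the starch and sucrose call (0.293) were lost; without a filter, the aquaporin (0.0579) and starch and sucrose (0.0638) calls were lost. With log2(FPKM + 1), which shrinks low values, the medians were 0.379 for heat shock, 0.672 for light harvesting, 0.482 for photosystems, 0.245 for aquaporins and 0.227 for starch and sucrose, and the last 2 calls were lost (0.0512 and 0.0571); log2(FPKM + 0.1) gave 0.672 for light harvesting, 0.586 for photosystems and 0.25 for aquaporins, and lost the photosystem (0.0769), aquaporin (0.08), ribosomal (0.0769) and starch and sucrose (0.0769) calls. With monocot hits only, the aquaporin median was 0.635, and the ribosomal (0.0812) and starch and sucrose (0.182) calls were lost. With 1 library left out, the ribosomal list median lay between -0.241 and 0.0818, reversed without plant alone replicate 3. The log2 fold changes of a CP26 antenna contig (CL2439.Contig6_zju, cluster sum 1.07) and sucrose-phosphate synthase 2 (Unigene2393_zju) lay between -2.94 and 6.30 and between -3.56 and 0.0928, reversed without plant alone replicate 2. These settings leave plant alone with 1 library, assumed to vary like the others. Over 18 alternatives each, heat shock passed in 15, light harvesting and WRKY in 14 each, photosystems in 11, aquaporins in 9, ribosome in 8, and starch and sucrose in 7. The difference in organism-list counts, -1908 CPM, lay between -3297 and -518 with 1 library left out and was -144 for Chlorella, Auxenochlorella and Coccomyxa only. Of the authors' 33532 calls, 17849 were at least 4-fold. With 2 against 3 libraries of this spread, changes of 16-fold were not recovered by edgeR in simulation.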

Other observations

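All tests of explanations in this part were chosen after the result was seen, except the test of switching contigs between pairs of libraries; the unigenes named first were also picked after their values were seen. A type 1 ribosome-inactivating protein with an Iris x hollandica hit (CL2971.Contig4_zju), of a protein family that depurinates ribosomal RNA, stood at 3.15 ± 1.13 CPM in plant alone (SD, n = 2) and 144 ± 34.4 in co-culture (SD, n = 3), a log2 fold change of 5.51 ± 0.50 (SE; DESeq2 adjusted p = 6.12e-23, edgeR adjusted p = 0.628). A second one, IRAb (CL10831.Contig5_zju), stood at 0.0835 ± 0.0441 and 6.77 ± 3.61 CPM. Both are single contigs of clusters that can share reads, and their cluster sums were not examined. The differences therefore hold for the contigs and need not hold for the genes.

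Among 54 unigenes with a hit to Chlorella, Auxenochlorella or Coccomyxa, 10 (18.5%) had no reads in plant alone and reads in all 3 co-culture libraries, against 1.58% of other unigenes (Fisher's exact test across unigenes, which are not independent, p = 1.23e-08). These 10 had 165, 89 and 129 reads in co-culture 1, 2 and 3, and included chlorophyll a-b binding protein unigenes (CL13014.Contig2_zju, Unigene13310_zju). The 54 unigenes together went the other way, at 252 ± 224 CPM in plant alone and 108 ± 26.1 in co-culture (exact permutation p = 0.3), with 410.7 CPM in plant alone 3.

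Ribosomal protein unigenes were lower in co-culture mainly where their protein hit lay outside monocots. Members on the organism lists and members with a monocot hit differed by -3.64 in median log2 fold change. RNA of another eukaryote in plant alone libraries could give such a difference. With unigenes on the organism lists left out, the ribosomal list kept a median of -0.174 (camera adjusted p = 0.0446). Those unigenes thus do not account for the whole shift of the list, but the organism lists do not hold every other eukaryote. The L13A unigene with a red alga hit was still tested when they were left out. With monocot hits only, the camera call was lost, and members with a monocot hit had a median of -0.10 in the main fit. Whether the remaining shift came from the plant's own genes was therefore not decided. Without plant alone replicate 3 the 275 members with a hit outside monocots had a median of 0.19 and the 30 on the organism lists 2.50, so most of the signal may belong to that library. The L13A and L10Ae unigenes, present in both plant alone libraries, are exceptions. Whether the alga changes what lives on the leaves was not tested.

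Many contigs had reads in one group and none in the other while their cluster sums moved little. Of 823 contigs called by DESeq2 in clusters of 2 or more, 150 (18.2%) had a cluster sum called the same way, which is consistent with reads divided differently between contigs. Contigs with at least 5 CPM in one library and none in another, at cluster sums within 2-fold, averaged 708.5 per pair of libraries of one group and 703.3 per pair across groups, a ratio of 1.01. The pair of plant alone libraries held 254, as did plant alone 2 with co-culture 1. Co-culture 3 held 971 and 858 with its own group and 1118 and 1032 with plant alone. Co-culture 1 went the other way, with 751 and 971 in its own group and 254 and 226 with plant alone. The libraries enter the averages within and across groups unequally, so the ratio cannot decide whether switching followed the groups. Transcript variants of individual plants and differences between library preparations both stay open, as these counts cannot tell them apart.

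Co-culture 3 went against co-culture 1 and 2 in light harvesting. Its median stayed at -0.531 or lower under 3 scalings, at -0.592 with library totals and without the 10 most abundant unigenes of each library (with TMM, leaving these out moved nothing), and at -0.926 with contigs summed per cluster, and it was at least 1.91 below the nearer of the other co-culture libraries in each. These values argue against scaling, a few abundant unigenes and contig switching as the cause. It also lay below both plant alone libraries, at 0.384 and -0.384. No biological explanation of this difference was tested.

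The 5 libraries allow 10 splits into 2 and 3, too few for a share under 0.05. DESeq2 called 1313 unigenes in the real split, and 3 splits gave as many, the real one included, the highest other being 3600 for co-culture 2 and 3 against the rest, which points to a structure of the samples beyond their groups. Camera passed 7 lists in the real split, and 6 splits gave as many, the real one included, with 9 as the highest other.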
